A study of Cairina moschata with 9 samples.

How the data were processed

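RNA from abdominal fat of Muscovy duck (Cairina moschata) was sequenced in 9 libraries, 3 each from birds of 12, 35 and 66 weeks of age. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made by a standard Illumina procedure. The series design text states that 3 birds of normal body weight were taken at each age, so the 3 libraries of an age are read as 3 birds. The sex of the birds, the library chemistry and the read length are not given in the sources used here. The labels carry 1 lane code per age (3 for 12 weeks, 4 for 35 weeks and 5 for 66 weeks), so lane and age cannot be told apart in any comparison.

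The deposited table gives 1 value in FPKM (fragments scaled by transcript length and by the number of mapped fragments) for each gene and library, per the file headers. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff were used. Their roles, the genome build, the annotation release and any scaling between libraries are not given in the sources used here. The gene models can therefore not be taken to be those of Muscovy duck. The table holds 14814 genes under Ensembl-type identifiers, of which 519 were listed at 0 in all 9 libraries. The files do not pair these identifiers with gene names. For that reason the 33 gene lists fixed before the data were examined (adipocyte, lipid metabolism, other cell types and others) could not be matched, and none of their set tests was run. The rule for the genes named in the text also asked for gene symbols. It was applied without that condition: for each comparison, the genes past the threshold whose 3 libraries of 1 age all lay above the 3 of the other, ranked by log2 fold change. Only the 2 largest in each direction were kept, fewer than the fixed rule asked for. Identifiers are printed for the 4 genes of the comparison of 66 with 35 weeks, and the values of others are given without an identifier. The fixed reference genes of adipose tissue, and the genes that came next in rank, could not be named either.

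FPKM values are not counts, so no count test was used. Values were taken as log2(FPKM + 1), and the 11491 genes with a mean of at least 1 FPKM over the 9 libraries were tested, which left out 3323. The 3 ages were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), so that they shared 1 estimate of the spread, with 6 residual and 2.03 prior degrees of freedom. The 3 pairwise contrasts and a moderated F test over the 3 ages were taken from that fit. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Single values per library were compared between ages by exact permutation tests, two-sided, whose smallest possible p for 3 against 3 is 0.1. No 2 libraries held identical values.

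A value of 0 in such a table can be a failed estimate or the absence of any fragment, also in genes with high values in other libraries. Of the tested genes, 666 were listed at 0 in at least 1 library. Of the genes with a mean of 1000 FPKM or more, 151 of 186 were above 0 in every library, so a gene is only said to be listed at 0, and its values are then given by library. The depth in reads is not given. Of 4944 low values in 1629 genes above 0 in 2 to 7 libraries, up to about 5 times the smallest value of the gene, 83.3% lay within 0.1 of a whole multiple of that value after the step of each library was taken out. Evenly spread values would give 20%, but the steps were estimated from these same genes, so 20% is not the chance level here. The ratio of these steps between libraries, each step being the value of 1 fragment, gave a relative depth of 0.89 (35-week replicate 1) to 1.289 (66-week replicate 2), with 1 as the mean of the libraries, a ratio of 1.448. These are ratios of fragment numbers only if no further scaling was applied between libraries, which is not given in the sources used here. The same estimate was made in classes of genes by the FPKM value of 1 fragment, which is larger for shorter gene models. On simulated fragments from 14000 genes, the largest error was 0.006 on the log2 scale in the classes between 1 and 50 FPKM. These computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the plots matplotlib 3.10.9.

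The limma fit was tested on simulated data built from the means and spreads of the 11491 genes for the comparison of 66 with 35 weeks, with 200 changed genes in each of 10 runs. It recovered 36% of the 2-fold changes, 69.8% of the 4-fold changes and 79.6% of the 8-fold changes, with 0 of the wrong sign. Of all its calls, 6.04% were of unchanged genes.

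Overlaps of calls between comparisons that share libraries were set beside the overlap of independent lists and beside 100 simulations of unchanged groups with the same libraries shared. In all simulated unchanged groups each gene was drawn independently of the others, so their range can be too narrow for genes that move together. The alternatives fixed before the data were examined were 2 other pseudocounts, 2 other filters, 2 scalings between libraries, 3 ways of estimating the spread, fits of only the 2 ages compared, the replicate number as a block, and 9 fits without 1 library each. A fit of only genes above 0 in every library, and the overlaps without 1 library each, were added after seeing the data.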

Results

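Abdominal fat, a large lipid depot of poultry, was profiled by RNA sequencing in Muscovy ducks of 12, 35 and 66 weeks of age, with 3 birds per age and 1 library per bird. The design asks how transcript abundance in this depot differs between the 3 ages. Between 10814 and 11291 genes reached 1 FPKM in a library, and between 1693 and 2039 were listed at 0. Relative depth, read from the value of a single fragment on the assumption that no further scaling was applied between libraries, ranged from 0.89 to 1.289, and its range overlapped between the ages. The files do not pair gene identifiers with names, so the genes below are given by identifier and by level only.

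Libraries of 1 age were more alike than libraries of different ages, with an exception at 12 weeks. Over the 11491 genes tested, Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, had a median of 0.903 between the 9 pairs of the same age and 0.870 between the 27 pairs of different ages. At 35 weeks it lay between 0.889 and 0.914, at 66 weeks between 0.889 and 0.906 and at 12 weeks between 0.835 and 0.908. Replicate 3 of the 12-week birds had a mean r of 0.844 with the other 12-week libraries and of 0.886 with the 35-week libraries. The median SD of a gene's log2 value was 0.278 at 12 weeks, 0.215 at 35 weeks and 0.211 at 66 weeks.

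**Figure D1:**
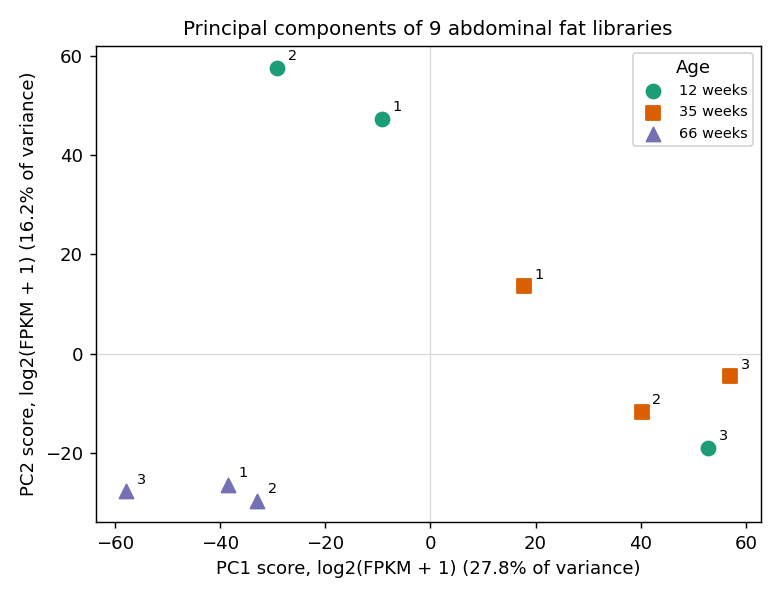
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1), with 1 point per library, colour and shape for age, and replicate numbers beside the points. The 66-week libraries sit at PC1 scores of -57.88 to -32.95 and the 35-week libraries at 17.77 to 57.01, while 12-week replicate 3, at 52.73, lies among the 35-week libraries and away from 12-week replicates 1 (-9.21) and 2 (-29.08).

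Between 12 and 35 weeks, 2 genes were higher at 35 weeks and 0 were lower (limma, adjusted p below the threshold of 0.05). ENSAPLG00000014341 rose from 4.79 ± 2.55 FPKM (SD, n = 3) at 12 weeks to 492 ± 79.8 FPKM (SD, n = 3) at 35 weeks, a log2 fold change of 6.51 ± 0.47 (SE) with an adjusted p of 0.00861 from limma. The other gene rose from 0.386 ± 0.445 to 10.2 ± 1.05 FPKM (SD, n = 3 each), a log2 fold change of 3.06 ± 0.30 (SE), with an adjusted p of 0.041 from limma. At an unadjusted p under 0.05, limma gave 930 genes higher and 470 lower at 35 weeks, where 575 in all would come from chance. The 3 libraries of 1 age all lay above the 3 of the other in 16.6% of the genes, where chance gives 10%. With 12-week replicate 3 left out, 316 genes were higher and 143 lower at 35 weeks, the 2 genes above among them, with a median log2 fold change of 1.34 in the former and -1.37 in the latter. The second gene was lost in 7 of the 9 fits without 1 library, and ENSAPLG00000014341 in 2, those without 35-week replicate 1 or 3. With 35-week replicate 1 left out, no gene was called, and the other single libraries left out gave between 1 and 8 calls. A pseudocount of 0.1 in place of 1 ended both calls, at 0 genes in either direction, and so did the replicate number as a block.

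Between 35 and 66 weeks, 130 genes rose and 274 fell (limma, adjusted p below 0.05), 404 of the 11491 tested. The genes that fell had a median log2 fold change of -1.53 and the genes that rose one of 1.05. A log2 fold change beyond 1 was seen in 223 of the former and 70 of the latter. ENSAPLG00000014341 fell from 492 ± 79.8 FPKM at 35 weeks to 2.30 ± 2.06 FPKM at 66 weeks (SD, n = 3 each), below its mean at 12 weeks, with a log2 fold change of -7.39 ± 0.47 (SE) and an adjusted p of 0.0016 from limma. ENSAPLG00000007105 fell from 5179, 4234 and 4329 FPKM in the 35-week libraries to 34.9 and 27.0 FPKM in 2 of the 66-week libraries, and was listed at 0 in 66-week replicate 3 (limma, log2 fold change -8.83 ± 1.78 (SE), adjusted p 0.0439). That call was lost without any 1 of the 6 libraries compared (adjusted p 0.0924 to 0.131), without 12-week replicate 2 (0.0519), with no filter and with either smaller pseudocount, with a range of 0.00759 to 0.131 over all alternatives. At 12 weeks this gene differed widely between birds, at 1410, 66.6 and 16.2 FPKM.

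ENSAPLG00000008256 had the opposite course. It rose from 7.29 and 6.08 FPKM in 35-week replicates 1 and 3, with replicate 2 listed at 0, to 128, 118 and 133 FPKM at 66 weeks (limma, log2 fold change 5.03 ± 0.79 (SE), adjusted p 0.0284), and its 12-week values were 59.4, 76.7 and 22.0 FPKM. Its call was likewise lost without any 1 of the 6 libraries compared (limma, adjusted p 0.0523 to 0.0954), with either smaller pseudocount and with the replicate number as a block (0.0541). The range was 0.00436 to 0.0954 over all alternatives. ENSAPLG00000001369 was listed at 0 in all 12-week and 35-week libraries and at 119, 62.2 and 99.8 FPKM in the 66-week libraries, with the smallest adjusted p of any gene, 3.48e-05 from limma against either age. The log2 ratios among its 3 values at 66 weeks lay within 0.063 of those of a single fragment on a very short gene model.

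**Figure D2:**
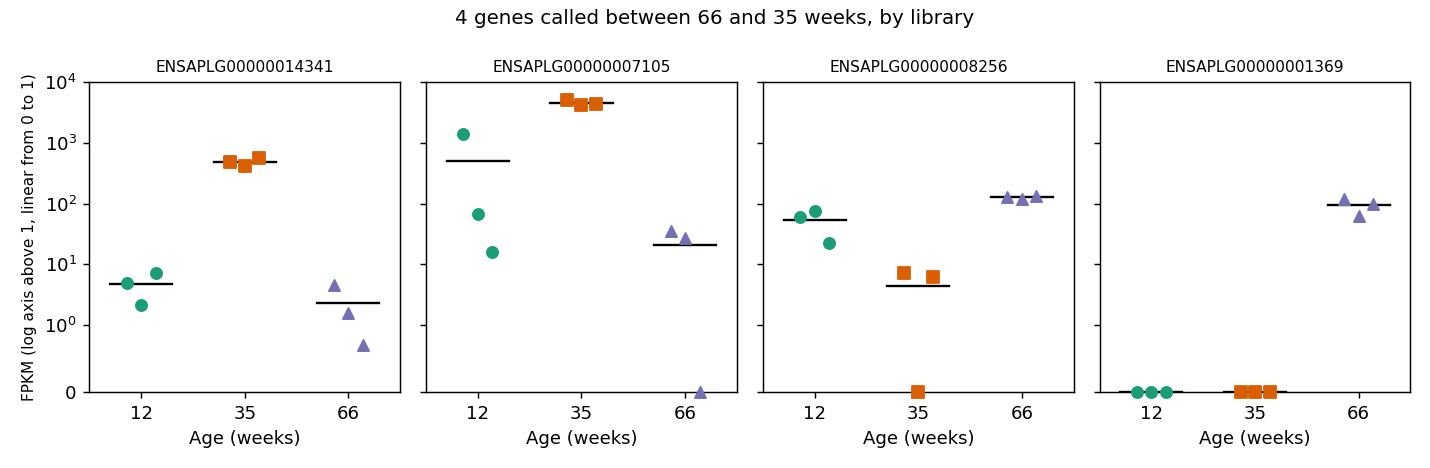
FPKM of 4 genes in each of the 9 libraries, with 1 point per library, a horizontal line at the mean of each age, and an axis that is logarithmic above 1 FPKM and linear below. The upper level of ENSAPLG00000014341 and ENSAPLG00000007105 is at 35 weeks, near 492 and 4580.5 FPKM, while ENSAPLG00000008256 is lowest at 35 weeks and ENSAPLG00000001369 is above 0 only at 66 weeks.

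Of the 274 genes that fell from 35 to 66 weeks, 268 had a positive fold change from 12 to 35 weeks, where unchanged groups simulated with the same libraries and list sizes gave 240 on average and 255 at most. The 12-week mean lay between the other ages, on the log2 scale, in 260 of the 274, against 207 on average and 222 at most. Of the 130 genes that rose, 106 had a negative fold change from 12 to 35 weeks, against 116 on average and 108 at least, and 106 had the 12-week mean in between, against 102 on average and 114 at most. Genes were simulated as independent of one another, so these extremes do not bound genes that move together. No excess or deficit is read from them. In 36.9% of all tested genes the 35-week and 66-week libraries did not overlap, where chance gives 10%. The number of calls depended on each of the 6 libraries compared: it fell from 404 to 2, 7 and 16 without 35-week replicates 1, 2 and 3, and to 45, 16 and 8 without 66-week replicates 1, 2 and 3. It was 1510 without 12-week replicate 3 and 229 without 12-week replicate 1, which enter only through the shared spread and the filter. With no filter on low values 63 genes were higher and 156 lower, and with the replicate number as a block 43 and 135. With only the 2 ages fitted there were 400 and 756, and with library weights 1195 and 1285.

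Between 12 and 66 weeks, 32 genes rose and 10 fell (limma, adjusted p below 0.05). ENSAPLG00000001369 led the genes that rose. The next gene by fold change was listed at 0 in 12-week replicates 1 and 3 and at 0.622 FPKM in replicate 2, against 4.97 to 8.09 FPKM in the 66-week libraries (limma, adjusted p 0.0368). The largest fall on the log2(FPKM + 1) scale was from 17.5 ± 7.18 to 0.886 ± 1.31 FPKM (SD, n = 3 each; limma, log2 fold change -3.44 ± 0.46 (SE), adjusted p 0.0382), in a gene that stood at 0.419 ± 0.0421 FPKM at 35 weeks. The next was from 11.2 ± 2.97 to 0.159 ± 0.021 FPKM (SD, n = 3 each; limma, adjusted p 0.0381), in a gene at 19.9 ± 12.1 FPKM at 35 weeks. With either smaller pseudocount the order of these 2 falls was reversed, at log2 fold changes of -5.07 and -5.41 with a pseudocount of 0.1. Of the 32 genes that rose, 18 had a mean of at least 100 FPKM, against 1242 of the 11491 tested. Genes at these levels were shifted together between the same libraries: 62% of those at 100 to 1000 FPKM and 80.1% of those at 1000 FPKM or more had a positive fold change, and the value of 1 fragment differed between these ages by up to 0.643 (log2) in the classes examined. Without 1 library at a time, the calls of the second gene that rose and of the largest fall were each lost in 8 of 9 fits, and that of the next fall in 7 of 9. Quantile normalization gave 5 higher and 3 lower, and median-ratio scaling 20 and 10. A fit of only the 2 ages gave 5 and 2, of which 1 and 2 were among the 32 and 10. The replicate number as a block left 1 and 0, while library weights gave 76 and 23. With each single library left out there were also fewer than 42 calls. There were 4, 7 and 14 without 12-week replicates 1, 2 and 3, and 1, 5 and 16 without 35-week replicates 1, 2 and 3. Without 66-week replicates 1, 2 and 3 there were 6, 6 and 4. Many of these were other genes. Of the 32 that rose, 1, 3 and 4 were called again without 12-week replicates 1, 2 and 3. Those called again were 1, 1 and 10 without the 35-week replicates, and 1, 1 and 1 without the 66-week replicates.

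The moderated F test over the 3 ages called 108 genes (limma, adjusted p below 0.05). By the order of their 3 means, without a test of each step, 60 were highest at 35 weeks, with a median log2 fold change of 1.07 from 12 to 35 weeks and of -1.74 from 35 to 66 weeks. A further 18 were lowest at 35 weeks, 25 had means in ascending order of age and 5 in descending order. Of the 60, 54 were also called between 35 and 66 weeks, and of the 25, 22 were called between 12 and 66 weeks and 14 between 35 and 66 weeks. Among all tested genes, 35.5% were highest at 35 weeks, 34.3% lowest, 17.8% in ascending and 12.3% in descending order. The median level was 136 FPKM in the 25 genes and 26.0 FPKM in the 60, a difference that was not tested. The count of 108 was 1151 without 12-week replicate 3, 69 without 12-week replicate 1, and between 2 and 10 without any 1 of the 35-week or 66-week libraries. With the replicate number as a block it was 2.

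For genes higher or lower at 66 weeks than at both other ages, the overlap of calls did not exceed the highest overlap in simulated unchanged groups. These groups share libraries in the same way. Of the genes higher at 66 than at 35 weeks and those higher at 66 than at 12 weeks, 13 were shared, where independent lists would share 0.362 and simulated unchanged groups, with lists of the same sizes, shared 10.9 on average and 17 at most. Of the genes lower at 66 weeks in both comparisons, 7 were shared, against 0.238 and against 5.64 on average and 9 at most. Both genes higher at 35 than at 12 weeks were lower at 66 than at 35 weeks, against 0.0477 and against 1.28 on average and 2 at most. A list of 2 genes cannot share more than 2, so this overlap could not have exceeded the simulated ones. The 3 libraries of an age are too few to split, so part of any excess may come from the libraries shared. Over all tested genes, the covariance of the log2 fold changes of 66 against 35 and 66 against 12 weeks was 0.414, beside 0.129 in the simulated groups. That of 35 against 12 and 66 against 35 weeks was -0.297 beside -0.128, and that of 35 against 12 and 66 against 12 weeks was 0.134 beside 0.130.

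Genes with the highest FPKM values differed in level between the ages as a class. FPKM is scaled by transcript length, so a high value can be few fragments on a short gene model. It need not mean an abundant transcript. Of the 186 genes with a mean of 1000 FPKM or more, 151 were above 0 in every library. The median over these 151 was 1516 ± 53.3 FPKM at 12 weeks, 1796 ± 126 FPKM at 35 weeks and 2315 ± 103 FPKM at 66 weeks (SD, n = 3 each). The sum of FPKM over all genes was 1312370 ± 135997, 1606170 ± 107047 and 1972450 ± 149720 at the 3 ages (SD, n = 3 each). For both measures the libraries of any 2 ages did not overlap, and each exact permutation p was 0.1, the smallest that 3 against 3 allows. The median of all tested genes was 16.3, 16.8 and 16.7 FPKM.

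The FPKM value of a single fragment also differed with age, in a way that depended on the gene. Relative to genes for which 1 fragment is worth 0.06 to 0.12 FPKM, the value in genes for which it is worth 3 to 10 FPKM was shifted by -0.22 ± 0.069 at 12 weeks, -0.07 ± 0.060 at 35 weeks and 0.29 ± 0.064 at 66 weeks (log2, SD, n = 3 each), from 49 genes. The 66-week libraries lay above all others, with an exact permutation p of 0.1 against either age.

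**Figure D3:**
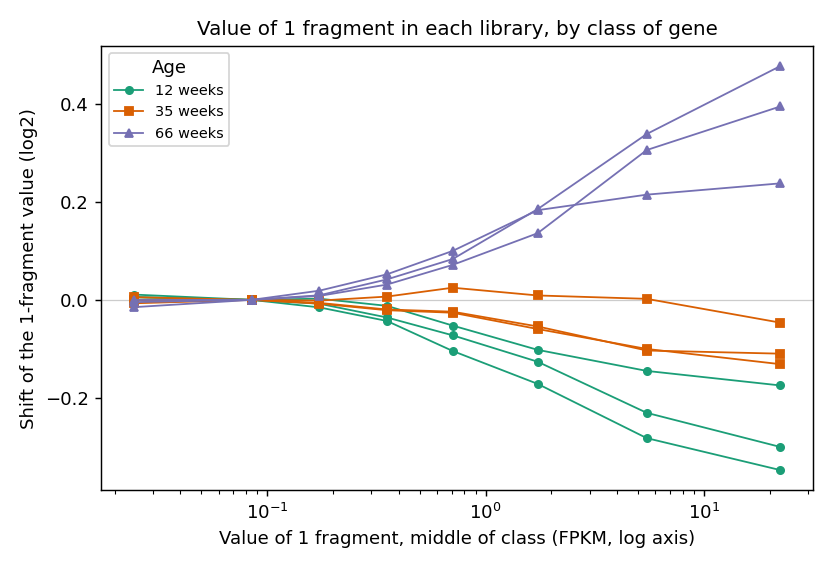
Shift of the value of 1 fragment (log2) in each of the 9 libraries, by the FPKM that 1 fragment is worth (log axis, middle of each class), relative to the class of 0.06 to 0.12 FPKM, with 1 line per library and colour for age. The lines of the 3 ages part toward high values, where the 66-week libraries exceed the 12-week libraries by a mean of 0.643 in the class of 10 to 50 FPKM.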

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

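All alternatives here were fixed before the data were examined, except the fit of only genes above 0 in every library and the overlaps without 1 library, which were chosen after seeing the data. Counts below are genes past an adjusted p of 0.05 with limma, and the cause of each change was not tested unless it is given. For the genes named or described by level in the text, 135 of the 203 values under the alternatives were past the threshold. All 203 kept the sign of the log2 fold change. The rule that chose these genes asked that all libraries of 1 age lie above all those of the other. Apart from the scalings between libraries, no alternative could then reverse the sign, so the kept sign is no evidence of stability. ENSAPLG00000014341 passed from 35 to 66 weeks in all 21 alternatives (adjusted p 0.000232 to 0.0193) and from 12 to 35 weeks in 17 of 21 (0.00206 to 0.0916), ENSAPLG00000007105 in 10 of 20 (0.00759 to 0.131), and ENSAPLG00000008256 in 11 of 20 (0.00436 to 0.0954). The second gene higher at 35 than at 12 weeks passed in 9 of 20 (0.00573 to 0.233). From 12 to 66 weeks, the second gene that rose passed in 8 of 19 (0.027 to 0.108), the largest fall in 7 of 21 (0.0112 to 0.16) and the next in 12 of 21 (0.00477 to 0.11).

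The 2 genes higher at 35 than at 12 weeks became 0 with a pseudocount of 0.1, 7 with 0.01, 5 with no filter, 1 with a mean of at least 5 FPKM, 1 with quantile normalization, 5 without the trend and 6 with only the 2 ages fitted. The count of 0 lower became 3 with a pseudocount of 0.01, 1 with no filter and 3 with only the 2 ages. From 35 to 66 weeks, no filter gave 63 higher and 156 lower, and only the 2 ages gave 400 and 756, a fit without the 12-week libraries. From 12 to 66 weeks, median-ratio scaling gave 20 higher, quantile normalization 5 higher and 3 lower (62.5% higher, against 76.2%), no trend 6 lower, and only the 2 ages 5 and 2. Library weights, which gave 12-week replicate 3 a weight of 0.282 and 35-week replicate 2 one of 3.77, gave 329 higher and 142 lower from 12 to 35 weeks, 1195 and 1285 from 35 to 66 weeks, 76 and 23 from 12 to 66 weeks, and 2148 over the 3 ages. Genes above 0 in every library gave 8 higher and 2 lower from 12 to 35 weeks, 16 lower from 12 to 66 weeks and 200 over the 3 ages. The overlaps of 13 higher and 7 lower at 66 weeks than at both other ages became 4 and 2 with quantile normalization, and the 2 genes highest at 35 weeks became 1, or 0 with a pseudocount of 0.1.

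Without 1 library at a time, the counts ranged from 0 to 316 higher and 0 to 143 lower from 12 to 35 weeks, 1 to 586 and 1 to 924 from 35 to 66 weeks, 1 to 13 and 0 to 3 from 12 to 66 weeks, and 2 to 1151 over the 3 ages. The overlaps ranged from 1 to 7 higher and 0 to 3 lower at 66 weeks than at both other ages, and from 0 to 254 higher and 0 to 97 lower at 35 weeks than at both. Except for the count of 13, which came without 35-week replicate 3, and the overlap of 3, likewise, the highest values came without 12-week replicate 3. The count of 3 lower from 12 to 66 weeks was also reached without 12-week replicate 2, 35-week replicate 3 or 66-week replicate 1.

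Replicate numbers did not pair the birds: the correlations of deviations of libraries with the same number ran from -0.0939 to 0.215 over 9 pairs, with 2 above 0.1. Those of the libraries numbered 1, which form 1 group of the split with 370 calls over the 3 ages, were 0.156, -0.0939 and 0.0266. With the replicate number as a block, limma called 0 higher from 12 to 35 weeks, 43 higher and 135 lower from 35 to 66 weeks, 1 higher and 0 lower from 12 to 66 weeks and 2 over the 3 ages. Under the block, 1 gene was higher and 0 lower at 66 weeks than at both other ages, and 0 were highest at 35 weeks. The set tests of gene lists were not run, since no identifier could be matched to a name. The depth in reads is unknown, which limits what can be said of genes with few fragments.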

Other observations

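Of the tests in this part, those of the shift of the value of 1 fragment, of an exchange of libraries, and of the gene listed at 0 in 6 libraries, and the overlaps without 12-week replicate 3, were chosen only after the result was seen.

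With 12-week replicate 3 left out, 254 of the 316 genes higher at 35 than at 12 weeks were lower at 66 than at 35 weeks, and 97 of the 143 genes lower at 35 weeks were higher at 66 than at 35 weeks. Only 1 gene rose in both steps and 1 fell in both. Independent lists would share 25.5 and 7.31, and simulated unchanged groups with the same libraries and list sizes shared at most 153 and 68. The library was left out for lying near the 35-week libraries, which by itself widens the step from 12 to 35 weeks, and the simulated groups hold no such choice, so these counts are values and no excess is read from them. With all 9 libraries, the genes higher and lower at 35 weeks than at both other ages were 2 and 0.

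Other splits of the libraries were fitted in the same way. Of the 10 splits of the 12-week and 35-week libraries, 7 gave at least the 2 calls of the real one. The highest of the others, 81 calls, exchanged 12-week replicate 3 with 35-week replicate 1, many times the real count, which points to a structure of the samples other than the age labels. For 35 and 66 weeks, 1 of the 10 splits, the real one, gave as many as 404 calls, and the highest other gave 2. For 12 and 66 weeks, 1 of 10 gave as many as 42, and the highest other gave 3. With 10 splits no share under 0.05 can be reached. Over the 3 ages, 2 of 100 splits drawn from 280, the real one included, gave at least 108 calls. A random split thus seldom gave as many, but this does not show age to be the source, since lane and age coincide. The other of the 2 splits gave 370 calls, again pointing to a structure of the samples other than age. Its 3 groups were replicate 1 of all 3 ages, then 12-week replicate 2 with 66-week replicates 2 and 3, and 12-week replicate 3 with 35-week replicates 2 and 3. One of its groups thus follows a replicate number and the others do not.

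Replicate 3 of the 12-week birds lay near the 35-week libraries. A library made and run with the 35-week libraries under a wrong label is argued against by the value of 1 fragment, whose shift in the class of 3 to 10 FPKM was -0.282 ± 0.0441 (log2, bootstrap SE) in this library, against -0.2304 and -0.1449 in the other 12-week libraries and -0.1033 to 0.0021 in the 35-week libraries. An exchange with a 35-week library is not excluded. Against it, the 200 genes that best separated the ages were chosen without the library judged and without 12-week replicate 3. At least 72.5% of them lay nearer the 35-week mean in each 35-week library (lowest in replicate 1, exact 95% binomial interval 65.8% to 78.6%). That interval counts genes of 1 library as independent, so it measures no spread between birds. The split that exchanged 12-week replicate 3 with 35-week replicate 1 goes the other way, with 81 calls against 2 for the real labels. A 35-week bird under a 12-week label, mixed up before the libraries were made, may be the cause: 86.5% of the 200 genes chosen without it lay nearer the 35-week mean in this library, against 57.5% to 84% in the 35-week libraries (72.5% to 94.5% with this library in neither mean) and 49.5% and 24.5% in the other 12-week libraries (36.5% and 24.5%). A 12-week bird whose fat differed from that of its group, by sex, feeding or the cells in the sample, could give similar values and was not tested.

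The median of the 151 genes at 1000 FPKM or more that were above 0 in every library rose from 12 to 66 weeks by 0.61 ± 0.047 (log2, SE). The largest shift in the value of 1 fragment between these ages was 0.643 ± 0.032 (log2, bootstrap SE over genes), in genes for which 1 fragment is worth 10 to 50 FPKM. That SE leaves out the spread between libraries, whose SD in this class was 0.089 at 12 weeks and 0.121 at 66 weeks (n = 3 each). The rise is within what a change in length correction between libraries could give to short gene models. Within ages, over the 9 libraries centred on the mean of their age, the shift in the class of 3 to 10 FPKM and the class median had a Pearson's r of 0.655 (exact permutation p = 0.106) and a Spearman's rho of 0.517 (exact permutation p = 0.199), and r was 0.581 without the 2 libraries farthest from the median shift. The lengths of the 151 genes are not used here, and lane and age coincide. Such a technical cause and a change with age therefore cannot be told apart. An effect of age stays open, untested.

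The gene with the smallest adjusted p, ENSAPLG00000001369, may rest on 1 fragment, or an equal small number, in each 66-week library. The log2 ratios of replicates 1 and 3 to replicate 2 were 0.93 and 0.68, and those of a single fragment, extrapolated to this level from classes of genes with few fragments, were 0.87 and 0.63. The largest deviation was 0.063, within the 0.1 set as the bound. The gene passed the threshold in all 20 alternatives that kept it. An expression that begins with age was not tested and stays open.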
